A study of Neurospora crassa with 42 samples.

How the data were processed

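Messenger RNA of the filamentous fungus Neurospora crassa was sequenced in 42 libraries that fall into 14 groups of 3, and the labels state that the 3 are biological replicates. Per the labels, mycelia were grown for 16 h in 100 ml of medium with 2% sucrose at 25 °C, 200 rpm and constant light, then washed and moved to medium without a carbon source (starvation) or with 2% Avicel, a microcrystalline cellulose. At 4 h there were 6 groups (18 libraries): wild type on starvation medium, wild type on Avicel, Δclr-1 and Δclr-2 on Avicel, and Δclr-3 and Pccg1-clr-2 on starvation medium. The last strain carries clr-2 under the promoter of the ccg-1 gene. At 10 h there were 8 groups (24 libraries), all on starvation medium: wild type, Δclr-3, Δos-1, Δos-2, Δcre-1 and the 3 double mutants Δos-1Δclr-3, Δos-2Δclr-3 and Δcre-1Δclr-3. Wild type is FGSC 2489.

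The deposited per-library values are FPKM (fragments per kilobase of transcript, scaled to the fragment total of the library), made by the authors and given for 9758 genes with the bounds of each estimate. The submitters' processing notes name HISAT2 2.0.5 and Cufflinks 2.2.1 and state no role for either. The loci are on build NC12; the annotation release, the strandedness of the libraries and the filters are not given in the sources used here, so values of overlapping or antisense genes are uncertain. The deposited whole-series table, also FPKM by the authors, holds 9598 loci, of which 9445 have a single identifier and 153 have several. Each of its 42 columns was 1 per-library file of the same group times a constant, with log2 factors from -0.37 to 0.47. In 31 columns the replicate number differed from that of the matching per-library file and in 11 it was equal; the numbers of the per-library files are used throughout, and the table served as an alternative scaling only. The deposited data hold FPKM and no counts, so depth was implied from the width of the FPKM bounds, assuming Poisson counting. The implied depth was 16.3 to 24.8 M (mega) fragments at 10 h (median 19.7) and 5.18 to 41.2 M at 4 h (median 17.1). Between 76.2 and 83.6% of the low implied counts lay within 0.05 of a whole number. No pair of replicates was a copy: the lowest chi-square per degree of freedom between replicates was 5.72, and at most 0.011% of values were identical. A value of 0 is given as listed, with no fold against it.

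Of the 9758 genes, 12 had a Cufflinks status other than OK in at least 1 library (61 values) and were dropped. Genes with a mean of at least 1 FPKM over the libraries of a fit were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend). The 4 h groups and the 10 h groups were fitted apart, each in 1 model with a term per group. The change of the Δclr-3 effect between times was fitted on the 4 groups it compares. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. A deleted gene was left out of the comparisons of its own strain. There were 18 comparisons: 14 of 3 against 3 libraries and 4 differences of differences over 12 libraries. The interaction of 2 deletions is the effect of the second deletion in the Δclr-3 background minus its effect in wild type, on the log2 scale. In text, ± after a log2 fold change is the standard error of the fit, ± after an FPKM is the SD of 3 libraries, and every adjusted p of a gene is from limma.

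Gene lists were written from memory of the field before the data were examined, as were the comparisons, the thresholds, the rule for named genes and the main set of alternatives. They hold 159 identifiers in 19 lists, all found in the deposited data; 116 carry a symbol in the reference annotation and 43 do not, and names missing there, clr-3 (NCU05846) among them, come from background knowledge. The lists are cellulose-degrading enzymes, lytic polysaccharide monooxygenases (LPMOs) with cellobiose dehydrogenase, hemicellulose-degrading enzymes, pentose catabolism, pectin-degrading enzymes, starch and sucrose degradation, hexose and xylose transporters, glyoxylate cycle and gluconeogenesis, glycolysis and fermentation, the quinate cluster, conidiation and hydrophobin genes (markers of conidia and aerial hyphae), light, clock and carotenoid genes, oxidative stress, endoplasmic reticulum folding, cell wall synthesis and nitrogen metabolism, with a further 3 given as values only: cellodextrin transporters, regulators of plant cell wall degradation and the osmosensing kinase cascade. A list of Avicel-induced genes, those called higher on Avicel in wild type, was derived from the 4 h libraries; at 4 h it is not independent evidence, and at 10 h it shares no library. Another 3 lists (ribosomal proteins, proteasome, glycerol metabolism) needed product text that the reference given lacks and were not analysed here.

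The 17 lists with a set test were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation; adjusted p values are over the lists of a comparison. Calls "adjusted over the list alone" use the p values of that list. The genes named are the targeted genes, the 6 largest increases and decreases per comparison among called genes whose groups did not overlap and whose higher group had at least 10 FPKM (4 each way for differences of differences), up to 4 called members of each list, and members of the regulator and osmosensing lists. Overlaps of called genes were compared with the product of the shares, and, for comparisons that share a control group, with 100 simulations of unchanged groups; Fisher's exact test was used where no library was shared. Tests on group means used exact or random permutations.

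The pipeline was tested on simulated data, with 200 of the genes changed. Each value was drawn around the mean of its gene with normal noise at the residual spread of that gene, equal in all groups. The simulated libraries hold no outlying replicate, so the shares called apply to such data only. Among genes changed 3-fold, 76 to 92% were called in the 4 comparisons tried, and among genes changed 16-fold, 98 to 100%; of unchanged genes at most 3 of 8016 were called. The alternatives fixed at the same time as the lists were a pseudocount of 0.1, no filter on low values, rescaling of each library by its median ratio to the gene-wise geometric mean, a fit on only the groups compared, limma without trend, the replicate number as a block, an estimated inter-gene correlation, and each replicate left out in turn. After the data were seen, the authors' rescaled table and the loss of the farthest library of each 4 h group were added, as were the double mutants against wild type. Splits of the samples into other groups were fitted in the same way. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.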

Results

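Transcript levels of 9758 genes were measured by RNA sequencing in 42 libraries of Neurospora crassa, 3 biological replicates in each of 14 groups. Of these, 6 groups were sampled 4 h and 8 groups 10 h after transfer from sucrose to Avicel or to medium without carbon. The implied depth was 5.18 to 41.2 M fragments per library at 4 h and 16.3 to 24.8 at 10 h. The series title names nutrient sensing and a kinase cascade that joins carbon and osmolarity sensing. The deleted genes encode the cellulase activators CLR-1 and CLR-2, their repressor CLR-3, the carbon catabolite repressor CRE-1, the osmosensing histidine kinase OS-1 and the MAP kinase OS-2. For pairs of replicates of a group, the SD across genes of their log2 ratio ran from 0.0878 to 1.01. The lowest mean correlation of a library with its own group was 0.932, in wild type on Avicel replicate 1 (implied depth 5.18 M fragments). Among the starved wild type libraries at 4 h it was 0.965, in replicate 2 (39.3 M).

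Each targeted gene was low in the strains that lack it. On build NC12, clr-1 (NCU07705, IV:2149157 to 2154036) was at 1.71 ± 0.210 FPKM in Δclr-1 and 108 ± 43.1 in wild type on Avicel (n = 3 libraries here and below). The clr-2 gene (NCU08042, IV:4001190 to 4004643) was at 0.0117 ± 0.0103 FPKM in Δclr-2 and 182 ± 9.86 in wild type on Avicel, and Pccg1-clr-2 held 298 ± 81.2 FPKM on starvation medium. For clr-3 (NCU05846, VII:4035638 to 4038540) the means of the strains that lack it lay between 0.123 and 1.27 FPKM, against 27.1 ± 0.151 in starved wild type at 10 h. The os-1 gene (NCU02815, I:9024259 to 9030833) was at 5.04 ± 0.132 FPKM in Δos-1 and 3.97 ± 0.505 in Δos-1Δclr-3, against 178 ± 10.0 in wild type. The os-2 gene (NCU07024, IV:4948586 to 4952179) was at 6.68 ± 1.59 and 4.75 ± 0.703 FPKM in the strains without it, against 215 ± 16.0. The cre-1 gene (NCU08807, IV:5176440 to 5178927) was at 1.24 ± 0.207 and 2.42 ± 0.162 FPKM without it, against 37.8 ± 4.23. In the groups that keep the gene, means ran from 27.1 to 142 FPKM for clr-1, 1.34 to 298 for clr-2, 22.5 to 408 for clr-3, 91.9 to 179 for os-1, 85.7 to 310.2 for os-2 and 15.8 to 155 for cre-1. The plot of clr-2, cbh-1 and ccg-13 gives 3 of the genes followed below in every library.

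**Figure D1:**
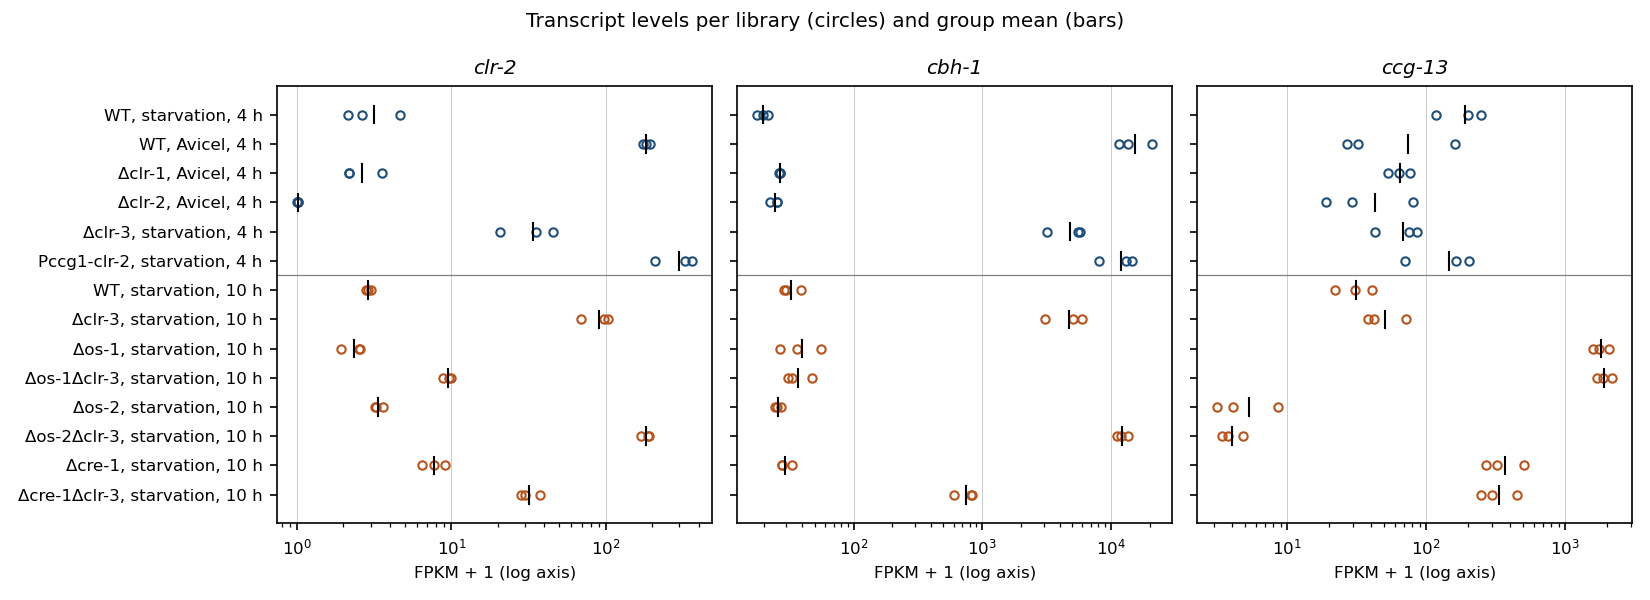
FPKM + 1 on log axes of clr-2, of cbh-1 (a cellobiohydrolase) and of ccg-13 (clock-controlled) in the 14 groups; circles are the 3 libraries of a group, bars the group means, blue 4 h and orange 10 h. The cbh-1 mean was 15319.8 FPKM in wild type on Avicel, 31.6 in starved wild type at 10 h, 4717 in Δclr-3, 36.1 in Δos-1Δclr-3 and 12228 in Δos-2Δclr-3.

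The first comparison asked which genes respond to cellulose in wild type at 4 h. The cellobiohydrolase gene cbh-1 (NCU07340) rose from 18.7 ± 1.90 FPKM on starvation medium to 15319.8 ± 4962 on Avicel, a log2 fold change of 9.56 ± 0.26 (adjusted p = 3.58e-13). The largest increase was that of the LPMO gene gh61-4 (11.72 ± 0.28), followed by the xylanase gene gh10-1 (10.50 ± 0.33) and the endoglucanase gene gh5-1 (10.49 ± 0.33). Of the cellulose-degrading enzymes, 11 of 14 measured members rose, and adjusted over the list alone also 11 (camera adjusted p = 2.29e-33). Of the LPMO and cellobiose dehydrogenase list, 10 of 15 rose and 1 fell, the same adjusted over the list alone, with cdh-1 at 8.33 ± 0.32 (camera 2.37e-30). All 18 measured hemicellulose-degrading enzymes rose, adjusted over the list alone also 18 (camera 5.7e-51). Among pectin-degrading enzymes 5 of 9 rose (6 adjusted over the list alone; camera 7.45e-10), led by the pectate lyase gene ply-2 at 5.70 ± 0.29.

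Transporter, protein folding and regulator genes rose as well. All 3 genes of the cellodextrin transporter list rose (3 adjusted over the list alone), with cdt-2 at 6.43 ± 0.32, cdt-1 at 5.20 ± 0.38 and clp-1 at 3.42 ± 0.43. The clp-1 gene has no symbol in the reference annotation. Its place in the list comes from background knowledge, and whether its product transports cellodextrins was not examined. All 5 endoplasmic reticulum folding genes rose (5 adjusted over the list alone; camera 3.16e-14), among them the chaperone gene grp-78 at 2.49 ± 0.22 and the disulfide isomerase gene pdi at 2.00 ± 0.17. Of 5 pentose catabolism genes 3 rose (3 adjusted over the list alone), led by the xylose reductase gene xyr-1 at 7.30 ± 0.58; camera gave 5.54e-05, and an adjusted p = 0.0923 with an estimated correlation. Of 10 regulators 5 rose, adjusted over the list alone also 5: clr-2 (5.94 ± 0.31), clr-3 (4.05 ± 0.20), vib-1 (2.06 ± 0.24), clr-1 (1.67 ± 0.28) and the xylanase regulator gene xlr-1 (1.46 ± 0.17). Of the 6 osmosensing cascade genes 0 were called by limma, and 0 adjusted over the list alone, with a median log2 fold change of -0.38 against -0.39 over all genes.

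Conidiation and hydrophobin genes fell on Avicel in 8 of 10 cases (8 adjusted over the list alone), with the hydrophobin gene eas at -2.56 ± 0.46; camera gave 0.00701, and an adjusted p = 0.0903 with an estimated correlation. Of 5 glyoxylate and gluconeogenesis genes 3 fell (3 adjusted over the list alone), with the isocitrate lyase gene acu-3 at -2.67 ± 0.38, while camera gave 0.304 for the list. In the outlying replicate 2 of starved wild type the median of this list lay 0.957 above the other two libraries on the log2 scale, and in replicate 1 on Avicel 0.458 above. Light, clock and carotenoid genes fell in 5 of 7 cases (6 adjusted over the list alone; camera 0.0665, and 0.00594 under median-ratio rescaling), and oxidative stress genes in 2 of 5 (2 adjusted over the list alone; camera 0.304). In nitrogen metabolism 1 of 5 rose (1 adjusted over the list alone), the nitrite reductase gene nit-6 at 1.98 ± 0.32; camera gave 0.0163, 0.0664 under rescaling, and an adjusted p = 0.0867 with an estimated correlation. Hexose and xylose transporters had 1 higher and 1 lower of 8 (the same adjusted over the list alone; camera 0.0311 upward, 0.366 under rescaling, and an adjusted p = 0.111 with an estimated correlation), and NCU06138 was the higher at 4.58 ± 0.50. Starch and sucrose degradation had 1 higher and 3 lower of 8 (the same adjusted over the list alone). Its median (-0.38) and mean (-0.33) were negative while camera pointed upward at 0.859. For glycolysis and fermentation (11 genes), the quinate cluster (6) and cell wall synthesis (8) limma called 0 genes, and 0 adjusted over the list alone, with camera at 0.315, 0.648 and 0.304. The glycolysis list had a median of 0.013, a mean of -0.006 and an upward camera direction.

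In all, 871 of 8271 genes were called between Avicel and starvation in wild type, 252 higher and 619 lower. The median over all genes was -0.39, so each change stands relative to that shift, and median-ratio rescaling gave 587 genes, 400 higher and 187 lower. A fit on only these groups called 291.

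On Avicel without clr-1 or clr-2, asking what each activator is needed for, the cellulase genes fell. In Δclr-1, cbh-1 was at 25.7 ± 0.327 FPKM against 15319.8 ± 4962 in wild type (log2 fold change -9.12 ± 0.26, adjusted p = 6.69e-13), and in Δclr-2 at 23.4 ± 1.69 (-9.25 ± 0.26, 4.26e-13). The gh61-4 gene fell in both, at -11.51 ± 0.28 in Δclr-1 and -12.07 ± 0.28 in Δclr-2. Of 14 cellulose-degrading enzymes 11 fell in each strain, adjusted over the list alone also 11 (camera 7.4e-32 and 6.4e-34). Of 15 LPMO and cellobiose dehydrogenase genes 10 fell in each, the same adjusted over the list alone (camera 3.38e-28 and 1.74e-30). Of 18 hemicellulose-degrading enzymes 12 fell in Δclr-1 and 13 in Δclr-2, adjusted over the list alone 13 in each (camera 6.71e-27 and 9.08e-36), and of 9 pectin-degrading enzymes 4 and 5, adjusted over the list alone 5 in each (camera 2.34e-07 and 2.78e-09). The 5 endoplasmic reticulum folding genes fell in both (5 adjusted over the list alone; camera 1.01e-12 and 7.01e-15), grp-78 at -2.09 ± 0.22 and -2.15 ± 0.22.

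The transporter gene cdt-1 fell too, at a log2 fold change of -4.53 ± 0.38 in Δclr-1 and -3.10 ± 0.38 in Δclr-2. The fall of cdt-2 was smaller, at -2.22 ± 0.32 in Δclr-1 and -1.13 ± 0.32 in Δclr-2, where its libraries overlapped with those of wild type. It kept means of 1740 and 3751 FPKM, against 8487 in wild type on Avicel and 90.5 in starved wild type at 4 h. Regulator genes fell as well: clr-2 at -6.16 ± 0.31 in Δclr-1, and in Δclr-1 and Δclr-2 clr-3 at -3.67 ± 0.20 and -2.64 ± 0.20 and vib-1 at -1.85 ± 0.24 and -1.68 ± 0.24. The acu-3 gene rose by 2.83 ± 0.38 and 2.28 ± 0.38, and 3 of 5 genes of the glyoxylate and gluconeogenesis list were called higher in each strain (3 adjusted over the list alone; camera 0.224 and 0.19, the latter 0.0479 under rescaling). In the outlying replicate 1 of Δclr-1 the median of this list lay 1.516 above the other two libraries, and in that of Δclr-2 at -0.866. In nitrogen metabolism 1 of 5 genes was lower in Δclr-2 (1 adjusted over the list alone; camera 0.0164, 0.0597 under rescaling, adjusted p = 0.071 with an estimated correlation). Of the 251 Avicel-induced genes measured, which were chosen on the same wild type libraries and are not independent evidence, 157 fell in Δclr-1 and 153 in Δclr-2 (158 and 153 adjusted over the list alone), and 5 and 2 rose (6 and 4).

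In Δclr-1 687 of 8270 genes were called, 482 higher and 205 lower, around a median of 0.33, and in Δclr-2 533 of 8270, 350 higher and 183 lower, around 0.37. Rescaling turned these splits to 152 higher and 314 lower of 466, and to 67 higher and 276 lower of 343. Fits on only the groups compared called 292 and 265, the count in Δclr-1 was 457 without wild type Avicel replicate 1 and 1064 without replicate 2, and that in Δclr-2 384 without replicate 1, 932 without replicate 2 and 811 without replicate 3. For Δclr-1, whose same-numbered libraries rose and fell together with those of wild type, the replicate number as a block gave 740.

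Set against each other on Avicel, Δclr-1 and Δclr-2 had few genes called between them. The mannanase gene gh5-7 was at 134 ± 7.15 FPKM in Δclr-1 and 1.31 ± 0.227 in Δclr-2 (log2 fold change 5.87 ± 0.26, adjusted p = 2.31e-09). NCU09689 was lower in Δclr-1, at 16.5 ± 1.79 FPKM against 164 ± 44.0 (-3.20 ± 0.22, 8.52e-07). Of 18 hemicellulose-degrading enzymes 1 was called higher, and 4 adjusted over the list alone (camera 6.98e-20). For 14 cellulose-degrading enzymes limma called 0, and 3 as lower adjusted over the list alone, with camera at 0.000395 and an adjusted p = 0.473 with an estimated correlation. The 3 genes of the cellodextrin transporter list were not called, and all 3 were lower adjusted over the list alone. limma called 8 of 8269 genes, 2 higher and 6 lower, with 110 at an unadjusted p under 0.05. That is less than a share of 0.05 of the genes tested. The model averages the spread over all 4 h groups. The SD across genes of the log2 ratio of replicates reached 1.01 in wild type on Avicel, 0.581 in Δclr-1 and 0.407 in Δclr-2. The standard errors here may therefore be too large, and the few calls do not show that the strains are alike. The count was 4 without Δclr-1 replicate 2 or 3 or Δclr-2 replicate 1, 5 without Δclr-2 replicate 2, 9 with the replicate number as a block, and 25 without the farthest library of each group. Among genes tested in both strains, 285 were higher and 167 lower in both, against 20.4 and 4.5 from the product of the shares, and 0 went opposite ways against 19.3. In 100 simulations of unchanged groups at most 0 genes were higher or lower in both, but hardly any gene is called between unchanged groups. That count therefore cannot show how far the shared wild type libraries add to the overlap. The covariance of the fold changes across genes, which are not independent replicates, was 0.5444 against a simulated 0.043. With 3 controls that cannot be halved, part of the excess can come from them.

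Loss of the repressor gene clr-3 was compared with wild type after 4 h of starvation, with no cellulose present. The cbh-1 gene was at 4823 ± 1441 FPKM in Δclr-3 and 18.7 ± 1.90 in wild type (log2 fold change 7.89 ± 0.26, adjusted p = 1.44e-11), the cellobiohydrolase gene gh6-2 rose by 8.41 ± 0.29, gh61-4 by 9.84 ± 0.28 and cdt-2 by 5.12 ± 0.32. The clr-2 gene rose by 3.44 ± 0.31, to 32.9 ± 12.5 FPKM, and was the 1 of 9 regulators called (1 adjusted over the list alone). Of the enzymes, 11 of 14 for cellulose, 11 of 15 LPMO and cellobiose dehydrogenase genes, 14 of 18 for hemicellulose and 4 of 9 for pectin rose, with equal counts adjusted over the list alone (camera 1.04e-20, 1.27e-17, 1.74e-22 and 0.000113). All 3 genes of the cellodextrin transporter list rose (3 adjusted over the list alone). The gene NCU08746 of the starch list rose by 4.32 ± 0.42.

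Nitrogen metabolism genes fell in 3 of 5 cases (3 adjusted over the list alone). The glutamate dehydrogenase gene am was at 15.9 ± 9.47 FPKM against 268 ± 17.6 in wild type (-4.13 ± 0.37, adjusted p = 1.79e-06), and the nitrate reductase gene nit-3 fell by 2.26 ± 0.40; camera gave 0.00746 and an adjusted p = 0.051 with an estimated correlation. Of 5 glyoxylate and gluconeogenesis genes 2 fell (2 adjusted over the list alone; camera 0.554 downward, median 0.048, mean -0.344), with the acetyl-CoA synthetase gene acu-5 at -1.82 ± 0.23, while in the outlying starved wild type library the median of this list lay 0.957 above the other two. For endoplasmic reticulum folding limma called 0 of 5 genes, and 0 adjusted over the list alone; camera gave 0.00746, and an adjusted p = 0.197 with an estimated correlation. In pentose catabolism 2 of 5 were called higher (2 adjusted over the list alone; camera 0.0394, 0.0828 under rescaling, adjusted p = 0.457 with an estimated correlation). NCU09968 was listed at 0 in all 3 Δclr-3 libraries and at 26.2 ± 0.862 FPKM in wild type. In all, 879 of 8270 genes were called, 262 higher and 617 lower, around a median of -0.19; rescaling gave 692, 351 higher and 341 lower, and without the farthest library of each 4 h group 1348 were called.

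Pccg1-clr-2, which holds clr-2 transcript without an inducer, was compared with wild type after 4 h of starvation. The xylanase gene gh10-1 rose from 1.01 ± 0.301 to 11498 ± 3627 FPKM (log2 fold change 12.44 ± 0.33, adjusted p = 2.92e-13), the LPMO gene gh61-5 by 10.47 ± 0.24 and cbh-1 by 9.20 ± 0.26. Of the enzymes, 10 of 14 for cellulose rose, 15 of 18 for hemicellulose, 6 of 9 for pectin, and of 15 LPMO and cellobiose dehydrogenase genes 10 rose and 1 fell, all equal adjusted over the list alone (camera 1.24e-25, 3.35e-40, 1.46e-12 and 1.24e-25). The ply-2 gene rose by 7.72 ± 0.29. The regulator genes clr-3, clr-1 and ara-1 rose, by 2.45 ± 0.20, 2.10 ± 0.28 and 1.20 ± 0.27 (3 of 9; 3 adjusted over the list alone). All 3 genes of the cellodextrin transporter list were called higher (3 adjusted over the list alone), with cdt-2 at 2.39 ± 0.32, and clp-1 at 1.22 ± 0.43 was called in only 2 of the 6 fits without a single library (adjusted p = 0.15 without Pccg1-clr-2 replicate 2).

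In the outlying replicate 1 the median of the glyoxylate and gluconeogenesis list lay 1.147 above the other two libraries. Of 5 endoplasmic reticulum folding genes 2 rose (2 adjusted over the list alone; camera 4.5e-08), grp-78 by 1.90 ± 0.22 and pdi by 1.68 ± 0.17. The glutamine synthetase gene gln-1 (-1.55 ± 0.24), the catalase gene cat-3 (-1.38 ± 0.32) and NCU05663 (-4.64 ± 0.18) fell, and NCU09968 and NCU07751 were listed at 0 in all 3 libraries. In pentose catabolism 1 of 5 genes was called higher (1 adjusted over the list alone; camera 0.0153, 0.0714 under rescaling, adjusted p = 0.436 with an estimated correlation). In all, 867 of 8270 genes were called, 228 higher and 639 lower, around a median of -0.29, and rescaling gave 619, 333 higher and 286 lower. Of the 251 Avicel-induced genes, 111 rose and 5 fell (112 and 7 adjusted over the list alone), and in Δclr-3 at 4 h 107 rose and 5 fell (108 and 7); the wild type starvation libraries that define this list are in both comparisons, so these counts are not independent evidence.

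After 10 h of starvation, the loss of clr-3 was compared with wild type again. The cbh-1 gene was at 4717 ± 1508 FPKM in Δclr-3 and 31.6 ± 5.61 in wild type (log2 fold change 7.13 ± 0.23, adjusted p = 1.04e-15). Increases of 8.96 ± 0.50 in gh61-4, 7.67 ± 0.30 in gh6-2, 5.64 ± 0.14 in cdt-2 and 5.30 ± 0.11 in cdt-1 went with a rise of 4.94 ± 0.14 in clr-2 and of 1.49 ± 0.08 in xlr-1, the 2 of 9 regulators called (2 adjusted over the list alone). Of the enzymes, 11 of 12 for cellulose, 9 of 13 LPMO and cellobiose dehydrogenase genes and 13 of 19 for hemicellulose rose, with equal counts adjusted over the list alone (camera 5.31e-25, 1.02e-14 and 2.96e-26). All 3 genes of the cellodextrin transporter list rose (3 adjusted over the list alone). Of 8 pectin-degrading enzymes 2 rose (2 adjusted over the list alone; camera 0.000239, adjusted p = 0.102 with an estimated correlation).

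Fermentation genes rose too, the pyruvate decarboxylase gene cfp by 3.08 ± 0.30 and the alcohol dehydrogenase gene adh-1 by 2.19 ± 0.16, the 2 of 11 called in their list (2 adjusted over the list alone; camera 1.28e-09). The invertase gene inv rose by 2.04 ± 0.20 (starch and sucrose degradation, 2 of 8 and 2 adjusted over the list alone; median -0.01, mean 0.66, camera 0.00575 upward, adjusted p = 0.102 with an estimated correlation). The acu-5 gene rose by 1.60 ± 0.09, 1 of 2 called of 5 in the glyoxylate list (2 adjusted over the list alone; camera 0.00135, 0.0567 under rescaling, adjusted p = 0.145 with an estimated correlation). The xyr-1 gene rose by 1.21 ± 0.10, the 1 of 5 called in pentose catabolism (1 adjusted over the list alone; camera 0.0276, 0.062 under rescaling, adjusted p = 0.142 with an estimated correlation). The catalase gene cat-3 (-2.11 ± 0.20), rca-1 (-2.11 ± 0.14) and app (-2.25 ± 0.27) fell, and NCU09968 was at 0.0114 ± 0.0108 FPKM against 31.1 ± 1.75. In all, 445 of 8015 genes were called, 235 higher and 210 lower, around a median of -0.29; rescaling gave 386, 320 higher and 66 lower, and a pseudocount of 0.1 gave 603, 254 higher and 349 lower.

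The Avicel response of wild type at 4 h and the Δclr-3 response at 10 h share no library. Of 233 genes higher on Avicel and 229 higher in Δclr-3 among the 7845 tested in both, 100 were in both, against 6.8 from the product of the shares (odds ratio 43.5, Fisher's exact p = 3.33e-98), and cbh-1, gh6-2, cdt-2 and clr-2 are among the genes above that rose in each. Of 577 and 206 lower genes 55 were in both, against 15.2 (4.96, 6.29e-18), and 5 went opposite ways against 23. Both comparisons had a negative median over all genes (-0.39 and -0.29), which favours lower calls in both. This overlap was not repeated under rescaling, and Fisher's exact test takes the genes as independent, which they are not. As a list, 100 of 233 Avicel-induced genes rose in Δclr-3 at 10 h and 2 fell, the same adjusted over the list alone (camera 2.68e-70).

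The Δclr-3 effect differed between 10 h and 4 h by 4.53 ± 0.41 for am (adjusted p = 0.000184), 3.42 ± 0.21 for acu-5 and 1.88 ± 0.29 for nit-3, which were lower in Δclr-3 at 4 h. The difference was -3.80 ± 0.50 for the cell wall protein gene ncw-5 and -3.32 ± 0.26 for cat-3. Of 5 nitrogen metabolism genes 3 were called higher (3 adjusted over the list alone; camera 0.00229, adjusted p = 0.0778 with an estimated correlation). Of 13 cellulose-degrading enzymes 1 was higher and 1 lower (the same adjusted over the list alone; camera 0.492). For glycolysis and fermentation limma called 0 of 11 genes, and 0 adjusted over the list alone, while camera gave 0.0412 and an adjusted p = 0.551 with an estimated correlation. In all, 532 of 8285 genes were called, 273 higher and 259 lower; rescaling gave 529, 329 higher and 200 lower. The count was 799 without starved wild type 4 h replicate 2 and 825 without the farthest library of each 4 h group.

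**Figure D2:**
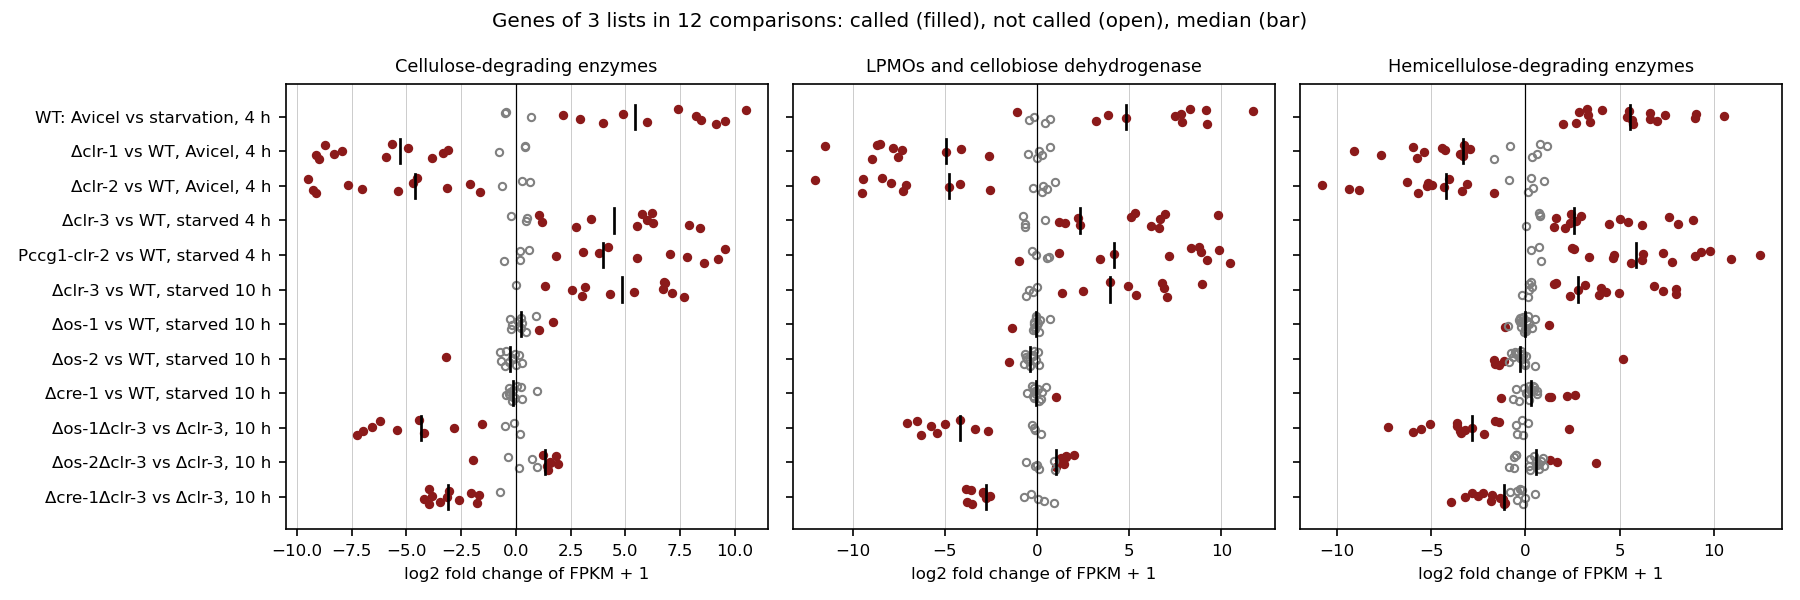
Log2 fold changes of FPKM + 1 for the cellulose-degrading enzymes, the LPMO and cellobiose dehydrogenase genes and the hemicellulose-degrading enzymes in 12 comparisons; each point is a gene, filled red where called and open grey where not, and the bar is the median of the list. The cellulose list has medians of 5.43 on Avicel in wild type, -5.29 and -4.61 in Δclr-1 and Δclr-2, 4.84 in Δclr-3 at 10 h, and -4.33, 1.33 and -3.10 when os-1, os-2 or cre-1 was missing as well.

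Loss of the osmosensing kinase genes was compared with wild type after 10 h of starvation. In Δos-1 the clock-controlled genes ccg-13 and ccg-14 rose by 5.89 ± 0.32 and 4.56 ± 0.25, ccg-13 from 30.3 ± 9.41 to 1810.4 ± 258 FPKM (adjusted p = 3.14e-11). The cell wall protein gene ncw-3 rose by 3.44 ± 0.15, eas by 1.68 ± 0.26 and the phosphoenolpyruvate carboxykinase gene acu-6 by 1.64 ± 0.27, while NCU04169 fell by 4.43 ± 0.45. Of 12 cellulose-degrading enzymes 2 were called higher (2 adjusted over the list alone), among them the β-glucosidase gene gh3-4 at 1.71 ± 0.26; camera gave 0.0213, 0.16 under rescaling, and an adjusted p = 0.722 with an estimated correlation. The clr-2 gene was at a log2 fold change of -0.31 ± 0.14 and was not called (adjusted p = 0.083). Conidiation genes had 2 higher and 1 lower of 10, the glyoxylate list 1 higher of 5, and starch and sucrose degradation 0 of 8 by limma, all equal adjusted over the list alone, each at camera 0.0024; with an estimated correlation the adjusted p = 0.167, 0.303 and 0.167. In all, 214 of 8015 genes were called, 127 higher and 87 lower, and 5 of 234 Avicel-induced genes were higher and 14 lower (the same adjusted over the list alone).

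In Δos-2 NCU04276, a gene without a symbol, went from 66.2 ± 23.4 to 6674 ± 737 FPKM (log2 fold change 6.68 ± 0.47, adjusted p = 1.18e-10). Of the glyoxylate and gluconeogenesis genes 3 of 5 rose (3 adjusted over the list alone), acu-6 by 3.54 ± 0.27 and acu-3 by 2.30 ± 0.23; camera gave 0.000153 and an adjusted p = 0.15 with an estimated correlation. Starch and sucrose degradation had 4 higher and 1 lower of 8 (the same adjusted over the list alone), inv at 2.09 ± 0.20 and the glucoamylase gene gla-1 at 1.55 ± 0.14; camera gave 0.00773, 0.0965 under rescaling, and an adjusted p = 0.15 with an estimated correlation. The am gene rose by 1.73 ± 0.16 (nitrogen metabolism, 1 of 5 and 1 adjusted over the list alone; camera 0.00159), cre-1 by 1.78 ± 0.14 and cfp by 2.63 ± 0.30 (glycolysis and fermentation, 2 of 11 and 2 adjusted over the list alone; camera 0.0376, adjusted p = 0.456 with an estimated correlation).

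Conidiation genes had 4 higher and 1 lower of 10 in Δos-2 (the same adjusted over the list alone), con-10 at -2.62 ± 0.26 and eas at 2.09 ± 0.26; camera gave 0.00159 and an adjusted p = 0.139 with an estimated correlation. The carotenoid gene al-1 rose by 2.08 ± 0.16, and the photoreceptor gene vvd fell by 1.63 ± 0.13. NCU10040 (-4.99 ± 0.25), ncw-5 (-3.76 ± 0.18) and gh3-4 (-3.20 ± 0.26) fell, the last as the 1 of 12 cellulose-degrading enzymes called (1 adjusted over the list alone; camera 0.912 upward, with a list median of -0.27). Of 234 Avicel-induced genes 9 were higher and 35 lower (the same adjusted over the list alone; camera 0.992 upward, with a negative list median of -0.27). In all, 861 of 8015 genes were called, 359 higher and 502 lower, around a median of -0.24, and rescaling gave 784, 480 higher and 304 lower.

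Δos-1 and Δos-2 shared part of their changes and were opposite in another part. Of 8014 genes, 53 were higher and 40 lower in both, against 5.7 and 5.4 from the product of the shares. The 100 simulations of unchanged groups gave at most 0 for each. With hardly any gene called in them, they cannot weigh the part of the shared wild type libraries. Under median-ratio rescaling 64 were higher and 24 lower in both. Another 29 went opposite ways, against 11.9 from the product of the shares. Of the 29, 26 were higher in Δos-1 and lower in Δos-2, and 3 the reverse. In the direct comparison ccg-13 was at 1810.4 ± 258 FPKM in Δos-1 and 4.31 ± 2.97 in Δos-2 (log2 difference 8.55 ± 0.32, adjusted p = 9.66e-15), NCU10040 differed by 7.69 ± 0.25, ncw-5 by 6.84 ± 0.18 and gh3-4 by 4.91 ± 0.26. The difference was -1.40 ± 0.14 for cre-1 and -1.95 ± 0.23 for acu-3. Of 5 glyoxylate and gluconeogenesis genes 2 were lower in Δos-1 (2 adjusted over the list alone; camera 0.0194, 0.092 under rescaling, adjusted p = 0.565 with an estimated correlation). Of 5 nitrogen metabolism genes 2 were lower (2 adjusted over the list alone; camera 0.0192, 0.0508 under rescaling, adjusted p = 0.0733 with an estimated correlation). In all, 727 of 8014 genes differed, 420 higher in Δos-1 and 307 lower, around a median of 0.12, and rescaling gave 693, 323 higher and 370 lower. The covariance of both fold changes across genes, which are not independent replicates, was 0.0954 against a simulated 0.0063, and part of the excess can come from the 3 shared controls.

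**Figure D3:**
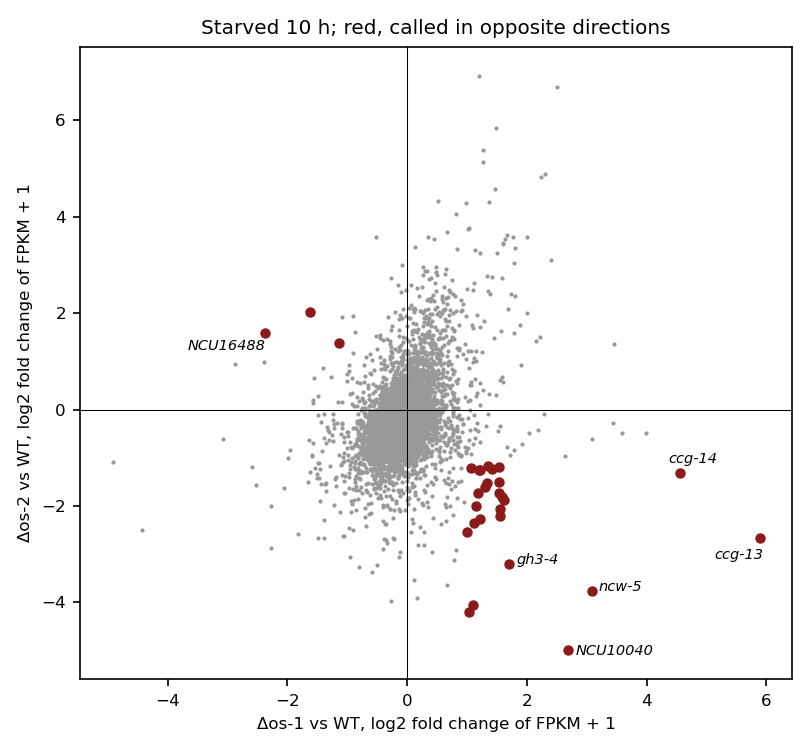
Log2 fold changes of FPKM + 1 against wild type after 10 h of starvation, Δos-1 on the horizontal and Δos-2 on the vertical axis; each point is a gene tested in both, and red marks the 29 called in opposite directions. Of these, 26 lie at the lower right, among them ccg-13 at 5.89 and -2.66 and ncw-5 at 3.08 and -3.76, and 3 at the upper left.

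Loss of the catabolite repressor gene cre-1 was compared with wild type after 10 h of starvation. NCU16673 rose from 8.62 ± 2.33 to 656 ± 518 FPKM (log2 fold change 5.74 ± 0.46, adjusted p = 1.93e-09) and poi-2 by 4.98 ± 0.30. Of the glyoxylate and gluconeogenesis genes 4 of 5 rose (4 adjusted over the list alone), acu-6 by 2.51 ± 0.27; camera gave 0.000151 and an adjusted p = 0.178 with an estimated correlation. The cfp gene rose by 3.27 ± 0.30 (glycolysis and fermentation, 2 of 11 and 2 adjusted over the list alone; camera 1.76e-08, adjusted p = 0.111 with an estimated correlation). The clr-2 gene rose by 1.41 ± 0.14, to 6.75 ± 1.31 FPKM, and the xylanase gene gh11-2 by 2.61 ± 0.28, while clp-1 fell by 1.50 ± 0.09. Hemicellulose-degrading enzymes had 4 higher and 1 lower of 19 (the same adjusted over the list alone; camera 0.00534, 0.0679 under rescaling, adjusted p = 0.554 with an estimated correlation). Starch and sucrose degradation had 2 higher of 8 (2 adjusted over the list alone; camera 0.00769, adjusted p = 0.178 with an estimated correlation).

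Of 12 cellulose-degrading enzymes limma called 0 in Δcre-1, and 0 adjusted over the list alone (camera 0.495 upward, with a list median of -0.14). For endoplasmic reticulum folding (5 genes) and cell wall synthesis (8) limma also called 0, and 0 adjusted over the list alone, while camera gave 0.00284 upward and 0.0483 downward; with an estimated correlation the adjusted p = 0.111 and 0.554, and the second was 0.0679 under rescaling and 0.063 with the replicate number as a block. Of 234 Avicel-induced genes 17 were higher and 14 lower (the same adjusted over the list alone; camera 0.00156 upward, adjusted p = 0.625 with an estimated correlation). NCU01402 (-4.60 ± 0.19) and con-10 (-1.91 ± 0.26) fell. In all, 478 of 8015 genes were called, 228 higher and 250 lower, around a median of -0.16, and rescaling gave 466, 293 higher and 173 lower.

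The double mutants asked how the Δclr-3 phenotype changes when a kinase or cre-1 is missing too. In Δos-1Δclr-3 against Δclr-3, cbh-1 was at 36.1 ± 8.93 FPKM against 4717 ± 1508 (log2 fold change -6.96 ± 0.23, adjusted p = 4.5e-15), and gh10-1 (-7.28 ± 0.30), gh6-2 (-7.24 ± 0.30) and cdt-2 (-3.03 ± 0.14) fell. The clr-2 gene fell by 3.23 ± 0.14, to 8.47 ± 0.620 FPKM, and xlr-1 fell by 1.08 ± 0.08, while cre-1 rose by 1.15 ± 0.14. Of the enzymes, 9 of 12 for cellulose and 9 of 13 LPMO and cellobiose dehydrogenase genes fell, and of 19 for hemicellulose 13 fell and 1 rose, with equal counts adjusted over the list alone (camera 1.62e-10, 1.29e-09 and 2.31e-11). With an estimated correlation the adjusted p = 0.0778 for each of these lists. Of 233 Avicel-induced genes 106 fell and 7 rose (the same adjusted over the list alone; camera 1.73e-32). Conidiation genes had 5 higher and 1 lower of 10 (the same adjusted over the list alone), eas at 2.82 ± 0.26, and ccg-13 rose by 5.29 ± 0.32; camera gave 0.0052 for the list, and an adjusted p = 0.122 with an estimated correlation.

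Pectin-degrading enzymes had 3 lower of 8 in Δos-1Δclr-3 (3 adjusted over the list alone; camera 0.0174, adjusted p = 0.259 with an estimated correlation), with ply-2 at -2.87 ± 0.26. Starch and sucrose degradation had 2 higher and 1 lower of 8 (the same adjusted over the list alone; camera 0.0257, adjusted p = 0.235 with an estimated correlation), and for cell wall synthesis limma called 0 of 8, and 0 adjusted over the list alone (camera 0.018, adjusted p = 0.259 with an estimated correlation). In all, 452 of 8014 genes were called, 249 higher and 203 lower. As a difference of differences, the effect of os-1 loss in the Δclr-3 background differed from that in wild type by -7.19 ± 0.33 for cbh-1, -7.68 ± 0.42 for gh6-2, -7.73 ± 0.70 for gh61-4, -3.12 ± 0.19 for cdt-2 and -2.92 ± 0.20 for clr-2. Starved wild type at 10 h held cbh-1, gh6-2 and clr-2 at 31.6, 33.0 and 1.89 FPKM, and Δos-1 at 38.7, 47.6 and 1.34. For these genes a fall as large as that in the Δclr-3 background could not occur in wild type. Their interaction therefore does not show that os-1 acts on them only without clr-3. Of 12 cellulose-degrading enzymes 10 were called lower in this interaction (10 adjusted over the list alone; camera 1.88e-26), as were 9 of 13 LPMO and cellobiose dehydrogenase genes (9 adjusted over the list alone; camera 3.82e-18), and 249 of 8014 genes in all, 120 higher and 129 lower.

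In Δos-2Δclr-3 the cellulase genes were higher than in Δclr-3. The cellobiohydrolase gene gh6-3 rose from 1066 ± 447 to 3749 ± 559.7 FPKM (log2 fold change 1.90 ± 0.24, adjusted p = 5.7e-07), gh5-1 by 1.84 ± 0.25 and cdh-1 by 2.00 ± 0.20. Of 12 cellulose-degrading enzymes 7 rose and 1, gh3-4 (-1.98 ± 0.26), fell, of 13 LPMO and cellobiose dehydrogenase genes 7 rose, and of 19 hemicellulose-degrading enzymes 3 rose, with equal counts adjusted over the list alone (camera 5.14e-07, 5.14e-07 and 1.07e-05; with an estimated correlation the adjusted p = 0.145, 0.123 and 0.189). The clr-2 gene rose by 1.04 ± 0.14, to 182 ± 12.2 FPKM, at a log2 fold change under 1 without Δos-2Δclr-3 replicate 2. The inv gene rose by 2.26 ± 0.20, acu-6 by 3.15 ± 0.27, am by 2.04 ± 0.16 and nit-6 by 1.33 ± 0.12, while ncw-5 (-3.41 ± 0.18) and ccg-13 (-3.63 ± 0.32) fell. Nitrogen metabolism had 2 higher of 5 (camera 2.73e-05), glyoxylate and gluconeogenesis 3 of 5 (1.07e-05, adjusted p = 0.12 with an estimated correlation) and starch and sucrose degradation 3 of 8 (0.00025, adjusted p = 0.0956 with an estimated correlation), all equal adjusted over the list alone.

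In all, 678 of 8014 genes were called in Δos-2Δclr-3 against Δclr-3, 218 higher and 460 lower, around a median of -0.29, and rescaling gave 587, 368 higher and 219 lower. Of 233 Avicel-induced genes 44 rose and 14 fell (the same adjusted over the list alone; camera 2.79e-14, adjusted p = 0.123 with an estimated correlation). The interaction of os-2 and clr-3 loss was 1.76 ± 0.33 for cbh-1, 2.59 ± 0.36 for gh5-1, -5.64 ± 0.66 for NCU04276 and -1.78 ± 0.19 for cre-1, and 8 of 12 cellulose-degrading enzymes were called higher in it (8 adjusted over the list alone; camera 2.57e-06, adjusted p = 0.202 with an estimated correlation). It was called for 370 of 8014 genes, 156 higher and 214 lower, and in the authors' rescaled table, used after the data were seen, for 350, 186 higher and 164 lower.

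In Δcre-1Δclr-3 the cellulase genes were lower than in Δclr-3. The gh6-2 gene was at 438 ± 95.3 FPKM against 7169 ± 2625 (log2 fold change -3.97 ± 0.30, adjusted p = 1.66e-10), and gh6-3 (-4.22 ± 0.24) and cdt-2 (-3.12 ± 0.14) fell. The regulator genes clr-2 (-1.48 ± 0.14), xlr-1 (-1.67 ± 0.08) and ara-1 (-1.46 ± 0.10) fell. Of the enzymes, 11 of 12 for cellulose fell, 8 of 13 LPMO and cellobiose dehydrogenase genes and 11 of 19 for hemicellulose, with equal counts adjusted over the list alone (camera 0.00295, 0.342 and 0.201, the last pair 0.0425 and 0.02 under rescaling). For the cellulose list the adjusted p = 0.608 with an estimated correlation. The acu-6 gene rose by 4.57 ± 0.27, cfp by 4.03 ± 0.30, the alternative oxidase gene aod-1 by 4.10 ± 0.30, the glyceraldehyde phosphate dehydrogenase gene gpd-1 by 1.65 ± 0.10, inv by 2.25 ± 0.20 and nit-6 by 1.89 ± 0.12. Glycolysis and fermentation had 3 higher of 11 and the glyoxylate list 3 of 5, equal adjusted over the list alone (camera 9.88e-08 and 0.00295); with an estimated correlation the adjusted p = 0.156 and 0.576.

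In all, 1166 of 8014 genes were called in Δcre-1Δclr-3 against Δclr-3, 359 higher and 807 lower, around a median of -0.38, rescaling gave 967, 638 higher and 329 lower, and the replicate number as a block again gave 1166. Of 233 Avicel-induced genes 98 fell and 10 rose (the same adjusted over the list alone; camera 0.093, 0.000896 under rescaling). The interaction of cre-1 and clr-3 loss was -4.11 ± 0.38 for the LPMO gene gh61-7, -4.03 ± 0.19 for the β-glucosidase gene gh1-1, -2.89 ± 0.20 for clr-2 and -1.60 ± 0.12 for xlr-1. It was called for 11 of 12 cellulose-degrading enzymes, all lower (11 adjusted over the list alone; camera 1.24e-06, adjusted p = 0.556 with an estimated correlation), and for 550 of 8014 genes, 211 higher and 339 lower, around a median of -0.21; rescaling gave 553, 320 higher and 233 lower.

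Against wild type, a comparison added after the data were seen, 3 of 12 cellulose-degrading enzymes were higher in Δos-1Δclr-3, 11 in Δos-2Δclr-3 and 8 in Δcre-1Δclr-3, with list medians of 0.16, 6.26 and 1.38. Of the 235 genes higher in Δclr-3, which were chosen against the same wild type libraries, 129, 206 and 154 were called higher and 2, 1 and 2 lower in these strains. Over all genes 326, 403 and 405 were called higher and 344, 1599 and 2217 lower, without rescaling. The plot of NCU04276, cfp and inv, chosen after their values were seen, gives genes that rose in Δclr-3 at 10 h and in which single 4 h libraries stood apart. NCU04276 was at 6277 FPKM in wild type Avicel replicate 1 and at 202 and 5.34 in the other two.

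**Figure D4:**
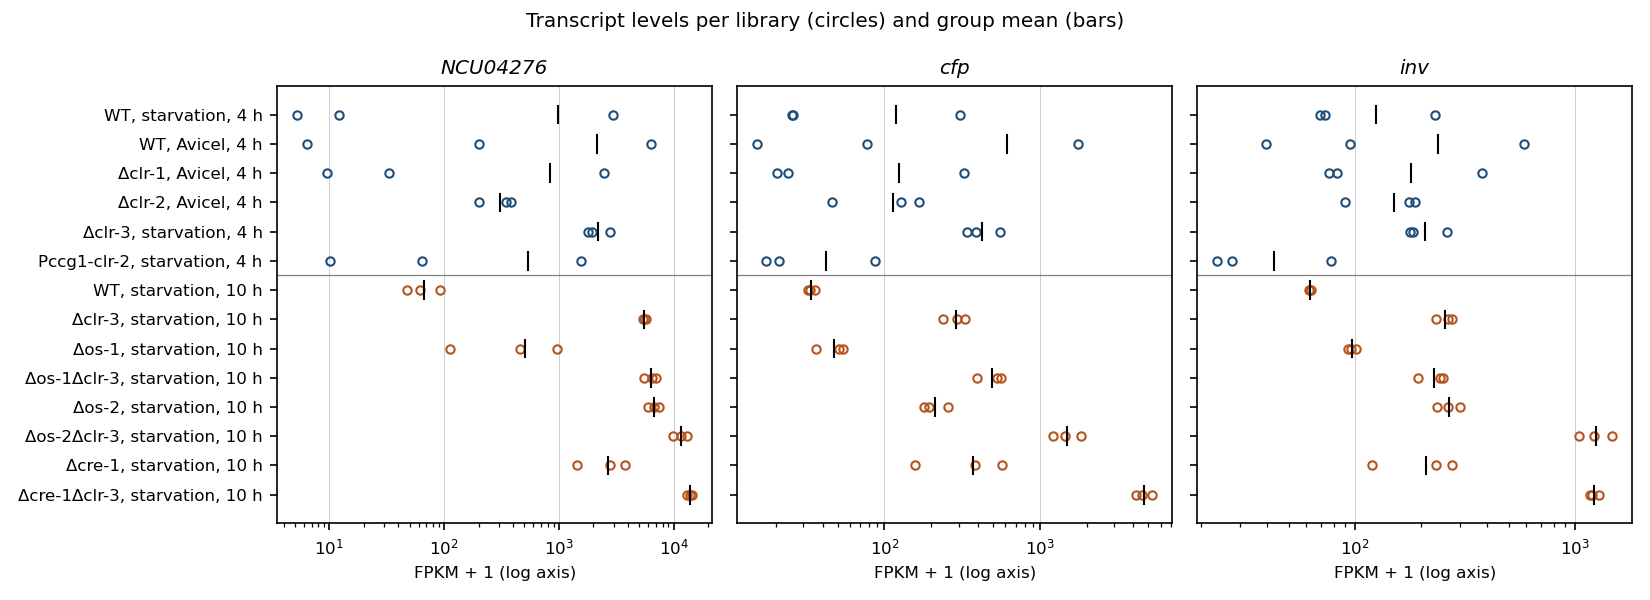
FPKM + 1 on log axes of NCU04276, of cfp (pyruvate decarboxylase) and of inv (invertase) in the 14 groups; circles are the 3 libraries of a group, bars the group means, blue 4 h and orange 10 h. At 4 h single libraries of wild type, Δclr-1 and Pccg1-clr-2 lie above the others of their group, and at 10 h the means of cfp are 32.7 FPKM in wild type, 286 in Δclr-3, 1502 in Δos-2Δclr-3 and 4678 in Δcre-1Δclr-3.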

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

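In this part the tests on the outlying 4 h libraries, those on NCU09968 and the rescaled count of opposite changes in Δos-1 and Δos-2 were chosen only after the result was seen. The results of the next paragraph are here because the effect of 1 deletion, or of 1 time, differed between groups by the test of the difference itself.

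The effect of os-1 loss differed between the Δclr-3 and the wild type background in 249 genes. On the log2 scale the difference was -7.19 for cbh-1, -7.68 for gh6-2, -7.73 for the LPMO gene gh61-4, -7.49 for the xylanase gene gh10-1, -3.12 for cdt-2 and -2.92 for clr-2, and 4.95 for NCU09968. In starved wild type at 10 h cbh-1, gh6-2 and clr-2 were at 31.6, 33.0 and 1.89 FPKM, too low for a fall as large as that in the Δclr-3 background. The effect of os-2 loss differed in 370 genes, by 1.76 for cbh-1, 2.59 for gh5-1, 2.80 for NCU10040 and 4.47 for NCU09968, and by -5.64 for NCU04276, -5.43 for NCU16673 and -1.78 for cre-1. The effect of cre-1 loss differed in 550 genes, by -4.11 for gh61-7, -4.03 for gh1-1, -3.98 for the xylanase gene gh11-2, -2.89 for clr-2 and -1.596 for xlr-1, and by 1.24 for nit-6 and 4.98 for NCU09968. The effect of clr-3 loss differed between 10 h and 4 h in 532 genes, by 4.53 for am, 3.42 for acu-5, 1.88 for nit-3, -3.80 for ncw-5, -3.32 for cat-3 and 1.501 for clr-2. The clr-2 value was called in 5 of 12 fits that left out a library, with an adjusted p = 0.0741 without Δclr-3 10 h replicate 2.

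Of 100 regroupings of the 12 libraries, the real one included, 15 gave at least as many genes as the os-1 interaction (249, highest other 908), 23 as the os-2 interaction (370, 2072), 8 as the cre-1 interaction (550, 2699) and 2 as the difference between times (532, 1355). The share was under 0.05 for the last alone. These regroupings also mix the main effects of strain and time, and those that called several times the real number point to a structure of the samples. This count therefore cannot decide on chance. With the additive effects of strain and time removed first, 1 of 100 regroupings, the real one, reached the real count in each case, with highest others of 137, 156, 239 and 165. This assumes an equal spread in all groups, which held only in part at 10 h. The SD across genes of the log2 ratio of replicates was 0.0878 to 0.110 in Δos-2 and 0.176 to 0.274 in Δcre-1. Only as far as that assumption holds is chance argued against for the 3 interactions. For the difference between times it was not decided. There the log2 ratios of wild type replicates had an SD across genes of 0.448 to 0.699 at 4 h and 0.109 to 0.177 at 10 h.

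The 14 comparisons of 3 against 3 libraries allow 10 splits each, too few for a share under 0.05, and in each 1 of 10, the real one, reached the real count. The real count and the highest other were 871 and 17 for Avicel in wild type, 687 and 1 for Δclr-1, 533 and 42 for Δclr-2, 8 and 1 for Δclr-1 against Δclr-2, 879 and 0 for Δclr-3 at 4 h, and 867 and 2 for Pccg1-clr-2. At 10 h they were 445 and 0 for Δclr-3, 214 and 0 for Δos-1, 861 and 0 for Δos-2, 478 and 7 for Δcre-1, and 727 and 0 for Δos-1 against Δos-2. Against Δclr-3 they were 452 and 0 for Δos-1Δclr-3, 678 and 0 for Δos-2Δclr-3, and 1166 and 0 for Δcre-1Δclr-3.

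The library with the lowest mean correlation with its own group was taken from each 4 h group. In those of starved wild type, wild type on Avicel, Δclr-1 and Pccg1-clr-2 it was high in NCU04276, cfp and inv, with NCU04276 at 2479 FPKM in Δclr-1 replicate 1 against 8.57 and 32.0; the deviations of these 4 libraries correlated at 0.266 to 0.496 in 6 pairs, and at -0.292 to 0.512 in the other 9. Low sequencing depth as a cause common to these libraries is argued against, since 1 of the 6 had the lowest implied depth of its group. That library was wild type Avicel replicate 1, at 5.18 M fragments against 19.6 and 18.5 M in the others of its group. For it low depth stays open. Sugar carried over from the preculture would keep the glyoxylate and gluconeogenesis list low, and that list lay above the 95th percentile of matched lists in 4 of the 4. The farthest libraries of Δclr-3 and Δclr-2 were not part of this test. In them the list lay at percentiles of 99.9 and 0.0, so for Δclr-2 replicate 1 sugar carried over stays open. A general rise of glycolysis genes, cfp and adh-1 aside, was seen in 1 of the 4. The design names no biological difference between replicates, so no biological explanation other than these was tested, and a difference in the state of single cultures stays open.

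NCU09968 (VI:309546 to 315476, build NC12) was at 15.59 FPKM or more in each wild type library and lower in all libraries of the other 11 groups, with means of 0.0671 ± 0.0885 FPKM in Δos-1, 0.0226 ± 0.00731 in Δcre-1, 14.1 ± 0.344 in Δos-2 and 9.49 ± 0.275 in Δos-2Δclr-3. Loss of clr-3 alone is argued against, since 4 groups with clr-3 intact had every library below 1 FPKM and Δos-2Δclr-3 was not near 0. Since the gene was near 0 in Δclr-3 as in Δos-1 and Δcre-1, its interactions of 4.95 and 4.98 go with a fall that could not occur again. In Pccg1-clr-2, for which the labels name no deletion, it was listed at 0 in all 3 libraries, and in Δclr-1 at 10.4 FPKM in replicate 1 and 0 in the other two. Another background of the strains other than wild type stays open, as the design holds a single wild type strain.

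Of the genes called in both Δos-1 and Δos-2, 29 changed in opposite directions, 26 of them higher in Δos-1, among them ccg-13, ccg-14, ncw-5, the cell wall protein genes acw-8 (1.23 and -1.25) and acw-12 (1.61 and -1.88) and gh3-4. A library-wide shift of the FPKM scale as the whole cause is argued against, since under median-ratio rescaling 30 genes were opposite, against 9.4 from the product of the shares. Noise in the shared wild type libraries moves both fold changes the same way, so its simulation could not decide on opposite changes. That OS-1 and OS-2 act on these genes in opposite ways is a hypothesis found and tested on the same libraries, and the strain background of each deletion strain stays open as an explanation.

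For the cellulose-degrading enzymes in Δos-2Δclr-3 against Δclr-3, a library-wide shift of the FPKM scale is argued against by a list median of 1.655 under rescaling, where that of Δos-1Δclr-3 was -4.33.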

How the results depend on the processing

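The authors' rescaled table and the loss of the farthest library of each 4 h group were chosen only after the results were seen; the other settings were set before the data were examined. Under a pseudocount of 0.1, no filter on low values, limma without trend and the replicate number as a block, the counts of called genes stayed within 1.5 times of those reported in 18 of 18 comparisons. Median-ratio rescaling moved 1 of 18, to 343 in Δclr-2 on Avicel. A fit on only the groups compared gave 291 for Avicel in wild type, 292 for Δclr-1 and 265 for Δclr-2, and 14 comparisons stayed within 1.5 times. The 3 that moved share wild type on Avicel, where the log2 ratio of replicates 1 and 3 had an SD of 1.01 across genes. The model used averages the spread over all 4 h groups, so the standard errors of these 3 may be too small, and those of Δclr-1 against Δclr-2 too large. For the difference of the Δclr-3 effect between times this setting is identical to the model used. The authors' rescaled table gave 557, 443 and 325 in the same order. Without the farthest libraries 25 genes were called for Δclr-1 against Δclr-2, 1348 for Δclr-3 at 4 h and 825 for the difference between times. The cause of the changes under the other settings was not tested.

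With a library left out in turn, the counts ran from 457 (without wild type Avicel replicate 1) to 1064 (without replicate 2) for Δclr-1, and from 384 (without replicate 1) to 932 (without replicate 2) for Δclr-2. They ran from 4 (without Δclr-1 replicate 2 or 3 or Δclr-2 replicate 1) to 8 for Δclr-1 against Δclr-2. For the difference between times they ran from 443 (without Δclr-3 10 h replicate 2) to 799 (without starved wild type 4 h replicate 2). Ranges within 1.5 times of the reported count were 707 to 1170 for Avicel in wild type, 708 to 1121 for Δclr-3 at 4 h, 696 to 951 for Pccg1-clr-2, 425 to 498 for Δclr-3 at 10 h, 197 to 241 for Δos-1, 823 to 928 for Δos-2, 470 to 521 for Δcre-1 and 671 to 788 for Δos-1 against Δos-2. For the double mutants against Δclr-3 they were 412 to 478 with os-1, 647 to 770 with os-2 and 1071 to 1285 with cre-1 missing, and for the interactions 200 to 276, 348 to 413 and 521 to 595.

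Of 987 values of named genes, none changed direction while called under the settings with a count here, and those that crossed the threshold were 4 with a pseudocount of 0.1 (3 lost, 1 gained), 7 without a filter (7 lost), 60 under rescaling (52 lost, 8 gained), 43 of 939 in the fits on only the groups compared (43 lost), 0 without trend and 2 with the block (2 lost). Of 656 called values of named genes, 77 were lost in at least 1 fit that left out a library, and 0 changed sign. Of 305 list tests, 66 were lost with an estimated correlation, 13 lost and 9 gained under rescaling, 3 lost and 2 gained without a filter, 4 lost and 5 gained of 288 in the fits on only the groups compared, and 1 lost and 1 gained both without trend and with the block.

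Replicate numbers were tested as a pairing of libraries: the correlations of same-numbered libraries were over 0.1 for all 3 numbers in 8 of 15 pairs of groups at 4 h and in 2 of 28 at 10 h. Among the comparisons they did so for Δclr-1 against wild type (block count 740), Δclr-1 against Δclr-2 (9) and Δcre-1Δclr-3 against Δclr-3 (1166). With the block al-2 (-1.46) and NCU00891 (1.24) in Δclr-3 at 4 h lost their call, and the labels do not state that the numbers pair the libraries. The lowest implied depth was 5.18 M fragments, in wild type Avicel replicate 1; the Avicel count was 707 without it and 1170 without replicate 2, and depth was not tested as the cause.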

Other observations

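The tests of this part were set before their results were seen; the light-regulated, transporter and catalase genes were picked for description from lists fixed in advance, after their values were seen.

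Light-regulated genes moved in both directions. Against wild type, the carotenoid gene al-1 rose by 2.08 ± 0.16 in Δos-2 and the photoreceptor gene vvd fell by 1.63 ± 0.13 (n = 3 libraries per group), 2 higher and 1 lower of 7 in their list, the same adjusted over the list alone (camera 0.329 upward, median -0.21, mean 0.31). Against Δclr-3, Δos-2Δclr-3 had al-1 at 1.10 ± 0.16, al-3 at 1.46 ± 0.20, vvd at -1.62 ± 0.13 and the blue-light-inducible gene bli-3 at -1.80 ± 0.10, 2 higher and 2 lower of 7, the same adjusted over the list alone (camera 0.989 upward, median -0.42). The change in vvd was also called in Δcre-1 (-1.16 ± 0.13) and, against Δclr-3, in Δcre-1Δclr-3 (-1.20 ± 0.13), and that in al-3 in Δos-1Δclr-3 (1.83 ± 0.20). All cultures were in constant light per the labels.

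Sugar transporter genes moved in both directions. NCU05897 rose by 1.98 ± 0.18 in Δos-2, and against Δclr-3 by 1.76 ± 0.18 in Δos-2Δclr-3 and 2.33 ± 0.18 in Δcre-1Δclr-3. NCU06138 was at -1.83 ± 0.12 in Δos-2, and against Δclr-3 at -1.68 ± 0.12 in Δos-2Δclr-3 and -1.37 ± 0.12 in Δcre-1Δclr-3. Of the 8 hexose and xylose transporters measured, 3 were higher and 2 lower in Δos-2, 1 and 2 in Δos-2Δclr-3, and 2 and 1 in Δcre-1Δclr-3, the same adjusted over the list alone (camera 0.418, 0.488 and 0.961, all upward, with list medians of 0.307, -0.110 and -0.469). Against wild type at 10 h, the catalase gene cat-3 was at -1.41 ± 0.20 in Δos-2 and -2.11 ± 0.20 in Δclr-3. In Δclr-3 at 4 h it was called higher, at 1.21 ± 0.32 (adjusted p = 0.0102). Against Δclr-3 at 10 h it was at -1.55 ± 0.20 in Δos-2Δclr-3, 1.24 ± 0.20 in Δos-1Δclr-3 and 1.32 ± 0.20 in Δcre-1Δclr-3.

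It was asked whether the loss of Avicel-induced expression in Δos-1Δclr-3 goes with dependence on clr-2. The 142 Avicel-induced genes that were also lower in Δclr-2 on Avicel had a median log2 fold change of -1.37 in Δos-1Δclr-3 against Δclr-3, and the other 90 had -0.57, a difference of -0.80 (one-sided permutation p = 2e-05 over 100000 permutations, genes not being independent). The 142 genes had also risen further in Δclr-3 at 10 h, at a median of 1.34 against 0.253. In a test added after the values were seen, with genes permuted only within 10 strata of that rise, the permuted difference had a median of -0.782 and p was 0.4557 over 10000 permutations. Dependence on clr-2 was therefore not separated from the rise in Δclr-3.

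It was also asked whether cellulase levels follow clr-2 levels over the 8 starved groups at 10 h. The mean log2 level of the cellulose-degrading enzymes correlated with that of clr-2 at a Pearson r of 0.943 (two-sided exact permutation p = 0.000744, adjusted 0.001488 over both) and a Spearman rho of 0.786 (0.02793, adjusted 0.02793). Without Δos-2Δclr-3 and Δclr-3, the groups with the highest clr-2, r was 0.811. In a split made after the values were seen, r was -0.277 over the 4 groups with clr-3 and 0.971 over the 4 without it. With clr-3 the mean log2 levels spanned only 1.22 to 2.94 for clr-2 and 2.72 to 3.44 for the cellulases. Without clr-3 they spanned 3.24 to 7.51 and 3.76 to 7.88. Over 4 groups in so narrow a range, the r with clr-3 cannot show a relation or its absence. The 4 groups without clr-3 held the highest levels of both, and the permutations exchanged all 8 groups. The permutation p values therefore do not separate a relation to clr-2 from an effect of clr-3 loss on both.

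The test did not show that genes within 100 kb of a deleted gene were called more often than genes around random positions: 22 of 236 were called, against a median of 16.0 and a 95th percentile of 25.0 over 10000 draws (one-sided permutation p = 0.1454, from random positions). The share was highest around clr-3, where 8 of 45 were called in Δclr-3 at 10 h (17.8% against 5.6% of all genes), 6 of the 8 being Avicel-induced genes, among them clp-1; around the other 5 deleted genes it was 2.6% to 11.4%, against 2.7% to 10.7% of all genes. In the authors' whole-series values 31 of 42 columns carry another replicate number than the matching per-library values.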
